A study of Rattus norvegicus with 12 samples.

How the data were processed

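Total RNA from PC12 cells, 250 ng per sample, had been labelled with biotin and hybridised to the Affymetrix Rat Transcriptome Array 1.0, with 1 sample on each of 12 arrays. The deposited values are log2 expression summaries per transcript cluster, here called features, and run from 0.95 to 13.82. The submitters' processing notes name Affymetrix Expression Console and RMA (robust multi-array averaging), without versions or options. The arrays were grouped by the labels into 4 groups of 3, and all 12 columns matched a sample. The labels number the replicates but do not say that they are separate cultures, so the p-values measure the spread between these samples, which may be technical. No pair of arrays held identical values (0 pairs).

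The table held 70580 features. Of these, 1738 control features were left out, and 34422 of the remaining 68842 were kept because their mean over all 12 arrays was at or above the median of all feature means, 4.63 log2 units. Gene symbols came from the array platform's annotation, checked against the RefSeq gene names of the rat assembly GRCr8, of which no coordinates were used. Over the 68842 features 23446 carried 1 symbol, 505 several and 44891 none, and 1 symbol was updated. Among features kept, 16054 carried 1 symbol, for 15313 genes, of which 648 had more than 1 feature. In 0 genes were features called in opposite directions. Adra2a, the adrenergic receptor that guanabenz is known to bind, was among the genes fixed for naming, but its feature lay under the filter and is not reported.

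A linear model with 4 group means was fitted to the deposited values of all 12 arrays in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes without a trend), with 8 residual degrees of freedom and a prior of 3.27. A feature counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over the features kept. The comparisons were induced against non-induced cells, each compound against vehicle in induced cells, compound 6 against compound 3, each compound group against non-induced cells, and an F-test for any difference among the 4 groups. Intervals are 95% intervals of the same model. Exact permutation tests of array scores are two-sided, and with 3 against 3 arrays their smallest p is 0.1. The features shared by both compounds were set beside the number expected for independent lists. Covariances of effects were set beside 100 simulated data sets without effects that kept the shared arrays, and were also computed from separate vehicle arrays on the 2 sides.

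Gene lists, 36 with 1020 entries, of which 942 are named on the array, were written from general knowledge of pathways, with markers of cell types for description. The 35 with at least 5 measured members were tested with camera at a preset correlation of 0.01, with 1 feature per gene (the one with the highest mean), and adjusted over the lists of a comparison. The list of mitochondrially encoded genes had 3 measured members and was not tested. The genes to name were set by a rule: in each of the first 4 comparisons the 5 features with 1 symbol that rose most and the 5 that fell most among those that passed without overlap of the groups, the 3 members with the smallest p in the direction of each list that passed, the strongest member called the other way, and Ppp1r15a, Ppp1r15b, Atf4, Ddit3, Hspa5, Htt and Adra2a. Where fewer than 5 features passed, those with the smallest p were added and said not to pass. Some genes that the rule names are not reported here. The groups, the comparisons, the lists, this rule and most alternatives were fixed before the data were examined.

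The alternatives were no filter, a filter at the 75th percentile (17216 features), median scaling, quantile normalisation, cyclic loess, an intensity trend with a robust prior, array weights, the replicate number as a block, a minimum change of 1.5-fold, only the arrays of the 2 groups compared, leaving out each array in turn, the mean of a gene's features, camera with an estimated correlation and fry. Chosen after seeing the data were a fit with each array's GC-rich background level as a covariate, and a fit of the features with 1 symbol alone. In data simulated with the same design the model recovered 82.1% of changes of 0.5 log2 units and 97.0% of changes of 1 in the induction comparison, with 19.4% at 0.3. For compound 3 against vehicle it recovered 31.3% at 0.3, 79.1% at 0.5 and 98.5% at 1, and for compound 6 31.3%, 76.1% and 100%. For compound 6 against compound 3 the shares were 28.4%, 77.6% and 100%. These data held noise drawn independently per feature with the same spread in all groups, and 150 features were called for compound 3. Far fewer passed in the real compound comparisons, which makes their threshold stricter, and the real vehicle arrays of induced cells varied more than the others. These shares therefore do not give the power of those comparisons. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.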

Results

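Messenger RNA was measured in PC12 cells, a rat pheochromocytoma line of adrenal chromaffin origin, on 12 whole-transcript rat arrays. The line carries a GFP-tagged huntingtin exon-1 fragment with 74 glutamines under doxycycline control, a cell model of Huntington disease. There were 4 groups of 3 arrays: non-induced cells with the vehicle DMSO, induced cells with DMSO, induced cells with compound 3, and induced cells with compound 6. The labels call both compounds guanabenz analogues, and both were given at 10 µM for 48 h. Doxycycline at 1 µg/ml went to the induced cells alone, so the effects of the fragment and of its inducer cannot be separated. Array medians lay between 4.61 and 4.70 log2 units, and the correlation between any 2 arrays was 0.995 to 0.998. The upper range differed: the 95th percentile was 10.29 to 10.32 on non-induced arrays and 10.32, 10.18 and 10.09 on induced DMSO 1, 2 and 3. On compound arrays it was 10.18 to 10.27. The sizes of changes in some gene lists depended on the scaling of the arrays. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.07 log2 units. In limma's F-test over 34422 features, 3540 differed somewhere among the 4 groups at an adjusted p under 0.05, 7463 at an unadjusted p under 0.05. Leaving out a single array gave 2087 (without non-induced 2) and 1874 (without non-induced 3). All differences are in log2 units, with 3 arrays per group and ± for the standard error.

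The first comparison asks what induction of the fragment changes in vehicle-treated cells. The gene that rose most by the fixed rule was Sparc, a secreted matrix glycoprotein, up 1.64 ± 0.12 (adjusted p = 9.03e-05), which is 3.11-fold. Slit2, an axon guidance ligand, rose by 1.02 ± 0.24 (adjusted p = 0.0196), a call lost in 4 of 21 alternatives (highest adjusted p 0.088), with non-induced 1 at 5.89 against 5.04 and 4.89 on the other non-induced arrays. Gstm2, a glutathione transferase, rose by 0.97 ± 0.09 (adjusted p = 0.000175). Ddr2, a collagen receptor kinase, and Olfml3, a secreted olfactomedin-like protein, rose by 0.84 ± 0.13 (adjusted p = 0.00175) and 0.78 ± 0.11 (adjusted p = 0.00133). P2ry12, a purinergic receptor for ADP, fell by 1.98 ± 0.15 (adjusted p = 9.03e-05). The calcium-dependent C2-domain genes C2cd4b and C2cd4a fell by 1.48 (adjusted p = 0.000134) and 1.37 (adjusted p = 0.000299). Dgkh, a diacylglycerol kinase, fell by 1.38 (adjusted p = 9.03e-05), and Adm, the vasodilator peptide adrenomedullin, by 1.36 (adjusted p = 0.000625). In all, 3120 features passed, 1447 higher and 1673 lower, and they cover 1110 named genes that rose and 760 that fell. Changes of at least 1.5-fold were mostly losses, with 523 features lower and 47 higher. With every array scaled to the same median the split was 744 higher and 1818 lower, with array weights 2980 and 2535, and without non-induced 1 it was 1463 and 1450, so the balance of gains and losses depends on the setting. Leaving out 1 array moved the count to 2064 (without non-induced 2), 1821 (without non-induced 3), 5165 (without induced DMSO 1) and 1815 (without induced DMSO 2).

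Induction lowered many of the genes that mark the catecholamine-producing chromaffin cell. Of 31 measured members of that list 19 fell and 1 rose, or 21 and 1 when adjusted over the list alone (median -0.42, camera adjusted p = 1.46e-11 and 0.353 with an estimated correlation). After quantile normalisation the median was -0.26. Gch1, which makes the cofactor of tyrosine hydroxylase, fell by 0.99 (adjusted p = 0.0001). The noradrenergic lineage factors Phox2a and Hand2 fell by 1.00 (adjusted p = 0.000635) and 0.94 (adjusted p = 0.000508). Another lineage factor, Gata3, rose by 0.26 (adjusted p = 0.0471), a call lost in 17 of 22 alternatives (highest adjusted p 0.183). Members named only after their values were seen were Dbh, which converts dopamine to noradrenaline and fell by 1.22 (adjusted p = 0.00104), Ddc, the aromatic amino acid decarboxylase (-1.14, adjusted p = 0.0144), the vesicular monoamine transporter Slc18a1 (-0.98, adjusted p = 0.0364) and the GDNF receptor Ret (-0.95, adjusted p = 0.00554). Tyrosine hydroxylase, Th, named in the same way, did not pass at -0.64 (adjusted p = 0.166). Several activity-dependent genes fell too. Among cAMP and CREB targets 8 of 18 fell and 1 rose, or 10 and 1 over the list alone (median -0.33, camera adjusted p = 6.8e-06 and 0.353 with an estimated correlation), with the salt-inducible kinase Sik1 at -0.96, the neuropeptide precursor Vgf at -0.71, the orphan nuclear receptor Nr4a1 at -0.70 and the G-protein regulator Rgs2 at 0.30. That list median ran from -0.65 to -0.148 over 21 alternatives. Of 30 immediate-early genes 9 fell and 1 rose, or 15 and 4 over the list alone (median -0.15, camera adjusted p = 9.07e-06 and 0.353 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, fell by 0.85 (adjusted p = 0.000444), Arc, a synaptic plasticity gene, by 0.62 (adjusted p = 0.0001), and Srf, the serum response factor, rose by 0.29 (adjusted p = 0.0483), a call lost in 14 of 22 alternatives (highest adjusted p 0.170).

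**Figure D1:**
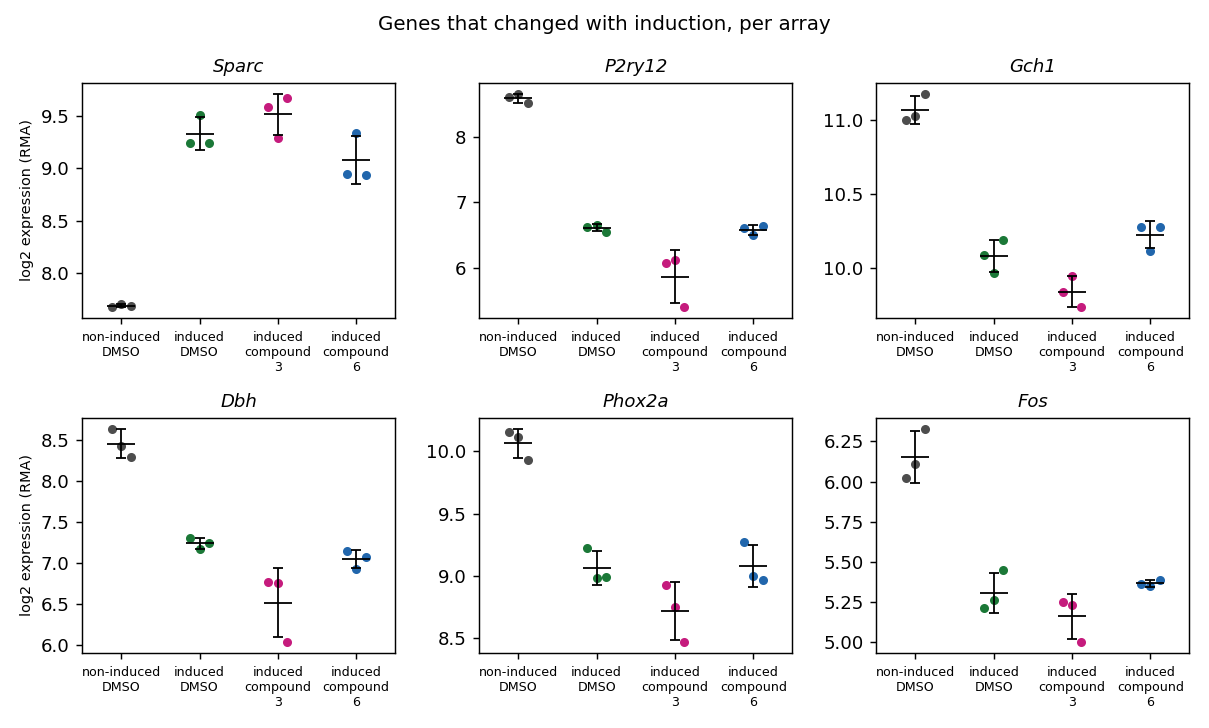
Log2 expression (RMA) of 6 genes on each array in non-induced DMSO, induced DMSO, induced compound 3 and induced compound 6 cells, with points for arrays and bars for the mean ± SD of 3 arrays. Sparc lies at a mean of 7.69 in non-induced and 9.33 in induced DMSO cells, and P2ry12, Gch1, Dbh, Phox2a and Fos lie lower in all 3 induced groups than in non-induced cells.

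Some neuronal genes fell as well, with list medians nearer to 0 than that of the chromaffin genes. In the neuronal differentiation list 5 of 27 genes fell and 1 rose, or 8 and 1 over the list alone (median -0.08, camera adjusted p = 0.000251 and 0.353 with an estimated correlation). They included Dpysl3 (-0.48), a growth-cone protein, the neurofilament gene Ina (-0.28) and the synaptic vesicle gene Syp (-0.37), while Syn1, another vesicle gene, rose by 0.27, a call lost in 15 of 22 alternatives (highest adjusted p 0.161). After quantile normalisation Ina lay at -0.064 and Syp at -0.151, and their calls were lost in 2 and 3 of 22 alternatives (highest adjusted p 0.617 and 0.193). In the list of targets of the neuronal repressor REST, which also holds Rest itself, 7 of 20 genes fell and 3 rose, or 8 and 5 over the list alone (median -0.10, camera adjusted p = 0.0178 and 0.366 with an estimated correlation). Over 21 alternatives that median ran from -0.147 to -0.02. The sodium channel subunit Scn3b and the granin Scg2 fell by 0.70 and 0.65. Rest, which is among the 3 counted as risen and is the repressor rather than a target, rose by 0.42. Of 23 genes known to be lowered in Huntington disease models 5 fell and 0 rose, or 7 and 1 over the list alone (median -0.01, camera adjusted p = 0.00999 and 0.353 with an estimated correlation). The median of that list ran from -0.413 to 0.0233 over 21 alternatives, so its sign is open, and its call was lost in 2. The fallen members included the phosphodiesterase Pde10a, at -0.41 (adjusted p = 0.0157), a call lost in 2 of 22 alternatives.

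Genes of cell division were lower after induction. Of 38 G2/M genes 37 lay lower, 17 fell and 0 rose, or 23 and 0 over the list alone (median -0.23, camera adjusted p = 1.14e-14 and 0.353 with an estimated correlation). That median was -0.15 after quantile normalisation. Nuf2, a kinetochore protein, fell by 0.64 (adjusted p = 0.00133), Top2a, the mitotic DNA topoisomerase, by 0.43 (adjusted p = 0.00372), and Kif4a, a chromosome-bound motor, by 0.32 (adjusted p = 0.0051). All 34 genes of DNA replication lay lower, 9 fell and 0 rose, or 17 and 0 over the list alone (median -0.15, camera adjusted p = 5.64e-13 and 0.353 with an estimated correlation). The hemimethylated-DNA reader Uhrf1 fell by 0.41 (adjusted p = 0.00304), the origin-licensing factor Cdc6 by 0.38 (adjusted p = 0.0116) and the G1/S cyclin Ccne1 by 0.21 (adjusted p = 0.00969), and the calls of Cdc6 and Ccne1 were lost in 3 and 2 of 22 alternatives. Of 12 histone genes 1, Hist3h2ba, fell by 0.53 and 0 rose, or 2 and 0 over the list alone (median -0.13, camera adjusted p = 5.31e-05 and 0.368 with an estimated correlation). Among glycolysis and hypoxia genes 5 of 34 fell and 0 rose, or 8 and 1 over the list alone (median -0.03, camera adjusted p = 0.000528 and 0.469 with an estimated correlation). They included the angiogenic factor Vegfa (-0.73) and the glucose transporter Slc2a3 (-0.40), which lay at -0.219 after quantile normalisation, the 1 of 22 alternatives that lost its call (adjusted p 0.174).

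Proteasome genes lay higher after induction, and several genes of the lysosome rose. All 33 measured proteasome genes lay higher, 14 rose and 0 fell, or 27 and 0 over the list alone (median 0.17, camera adjusted p = 1.38e-09 and 0.366 with an estimated correlation). That median was 0.14 after median scaling and 0.27 after quantile normalisation. The regulatory-particle subunits Psmd3 and Psmd11 rose by 0.41 (adjusted p = 0.00225) and 0.29 (adjusted p = 0.00318), and the core subunit Psmb4 by 0.26 (adjusted p = 0.00875). Of 39 autophagy and lysosome genes 9 rose and 3 fell, or 18 and 5 over the list alone (median 0.12, camera adjusted p = 0.00999 and 0.449 with an estimated correlation). Gabarapl1, an autophagosome protein, rose by 0.67 (adjusted p = 0.000162), the lysosomal proteases Ctsd and Ctsl by 0.46 and 0.37, and the proton pump subunit Atp6v1b2 fell by 0.54. Among targets of the oxidative stress factor NRF2 8 of 28 rose and 1 fell, or 12 and 1 over the list alone (median 0.12, camera adjusted p = 0.000458 and 0.368 with an estimated correlation). The growth inhibitor Osgin1, the glutathione transferase Gstp1 and the biliverdin reductase Blvrb rose by 0.49, 0.47 and 0.27, while haem oxygenase Hmox1 fell by 0.57 (adjusted p = 0.000625). In the metallothionein and metal list 3 of 10 rose and 1 fell, or 6 and 1 over the list alone (median 0.23, camera adjusted p = 0.0426 and 0.353 with an estimated correlation). The brain metallothionein Mt3 rose by 0.34, the zinc importer Slc39a10 by 0.24 and the transferrin receptor Tfrc by 0.21, and the calls of Mt3 and Tfrc were each lost in 7 of 22 alternatives and that of Slc39a10 in 4. Of 16 genes of ubiquitin and ER-associated degradation 3 rose and 0 fell, and that list did not pass camera (adjusted p = 0.283).

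Genes of cholesterol synthesis and of the mitochondria lay higher too. Of 21 cholesterol biosynthesis genes 6 rose and 0 fell, or 11 and 0 over the list alone (median 0.18, camera adjusted p = 0.000614 and 0.535 with an estimated correlation). Lss, which closes the sterol rings, rose by 0.51 (adjusted p = 0.0106), and the mevalonate pathway genes Mvk and Mvd by 0.25 (adjusted p = 0.00645) and 0.25 (adjusted p = 0.0156), where the calls of Mvd and Lss were lost in 3 and 1 of 22 alternatives. Among nuclear genes of oxidative phosphorylation 5 of 48 rose and 0 fell, or 7 and 0 over the list alone (median 0.08, camera adjusted p = 0.000295 and 0.353 with an estimated correlation), with the complex I subunit Ndufb10 at 0.32 and the oxidase subunits Ndufa4 and Cox5a at 0.19 and 0.17. The calls of Ndufa4 and Cox5a were lost in 11 and 9 of 22 alternatives. The mitochondrial ribosome list also covers translation and holds the protease subunit Clpx, which is not a ribosome gene. Of its 41 genes 1, Mrpl2, rose and 1, Clpx, fell, with 0 either way over the list alone (median 0.09, camera adjusted p = 0.0352 and 0.517 with an estimated correlation). Mrpl2 was lost in 17 of 21 alternatives and Clpx in 20 of 22. Among genes of the eIF2α stress pathway named in advance, the stress-induced phosphatase subunit Ppp1r15a lay at 0.15 ± 0.05 (adjusted p = 0.0752) and did not pass. The constitutive subunit Ppp1r15b, the stress factors Atf4 and Ddit3 and the chaperone Hspa5 lay at 0.00 (adjusted p = 1), -0.03 (adjusted p = 0.805), -0.04 (adjusted p = 0.86) and 0.02 (adjusted p = 0.858), and the signs of Ppp1r15b, Atf4 and Hspa5 flipped between scalings of the arrays. The rat Htt feature lay at 0.10 (adjusted p = 0.615) and whether its probes also bind the introduced human fragment was not tested. In all 17 of 35 lists passed camera with its preset correlation, 7 higher and 10 lower, and 0 passed with a correlation estimated from the data. Of 21 alternatives, that one included, 7 lost the metal list, 5 the mitochondrial ribosome, 3 the glycolysis list and 2 each the lysosome, REST, immediate-early and Huntington lists. Rotation testing with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, passed 20 lists, 16 of them among the 17.

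**Figure D2:**
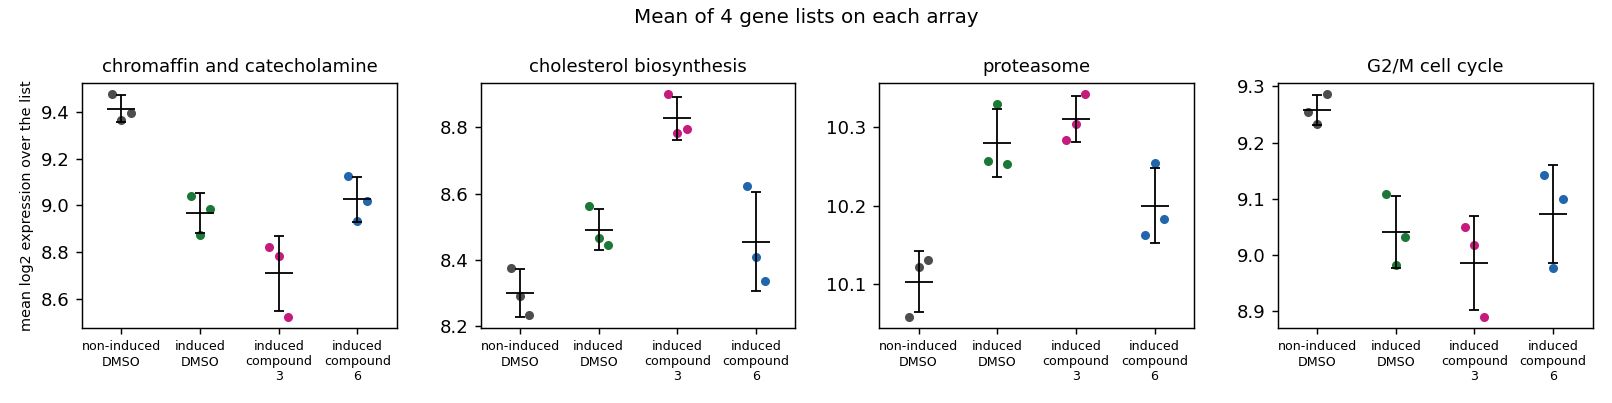
Mean log2 expression over 4 gene lists on each array, with points for arrays and bars for the mean ± SD of 3 arrays, in non-induced DMSO, induced DMSO, induced compound 3 and induced compound 6 cells. The cholesterol biosynthesis mean was 8.30 in non-induced, 8.49 in induced DMSO, 8.83 in compound 3 and 8.45 in compound 6 cells, and the chromaffin mean was 9.41, 8.97, 8.71 and 9.03.

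The comparison of compound 3 with vehicle asks what the compound changes in induced cells. Vdr, the vitamin D receptor, fell by 1.04 ± 0.06 (95% interval -1.17 to -0.91, adjusted p = 5.76e-05), with no overlap between the groups. Ptprr, a MAP kinase phosphatase, fell by 0.55 (adjusted p = 0.0159), Itga1, a collagen-binding integrin, by 0.61 (adjusted p = 0.0492), and Kcnh3, a voltage-gated potassium channel, by 0.44 (adjusted p = 0.0484). Of 8 features that passed, 2 rose and 6 fell, against 2509 at an unadjusted p under 0.05, where chance gives 1721. Arrays of the 2 groups did not overlap in 9.94% of features, where chance gives 10%. The other 4 carry no gene name. Singled out after their values were seen, TC1500001407.rn.1 rose by 1.05 and TC0700003826.rn.1 fell by 0.94. The latter's identifier is next to that of the Vdr feature, TC0700003827.rn.1, so the 2 calls need not be separate genes. Vdr passed in all 22 alternative settings, with values from -1.10 to -0.97, whereas Ptprr was lost in 6 and Itga1 and Kcnh3 in 17 each. Leaving out 1 array gave 2 features (without induced DMSO 2, induced DMSO 3 or compound 3 array 2), 3 (without non-induced 1 or 2, induced DMSO 1, compound 3 array 3, or compound 6 array 2 or 3), 4 (without non-induced 3 or compound 3 array 1) or 6 (without compound 6 array 1). Not all were among the 8, which shared 2 of the 3 without induced DMSO 1, 3 of the 4 without non-induced 3 and 4 of the 6 without compound 6 array 1.

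As a group, sterol synthesis genes lay higher with compound 3 than with vehicle. All 21 cholesterol genes lay higher, with 0 passing over all features and 18 over the list alone (median 0.35, camera adjusted p = 4.95e-24 and 0.292 with an estimated correlation). The fry adjusted p for this list was 0.0242. Below the threshold for single genes were the squalene epoxidase Sqle at 0.50 ± 0.08 (adjusted p = 0.0776), the isopentenyl isomerase Idi1 at 0.56 ± 0.08 (adjusted p = 0.0776) and the sterol reductase Tm7sf2 at 0.42 (adjusted p = 0.111). Of 39 lysosome and autophagy genes 29 lay higher, 0 passed and 12 were higher over the list alone (median 0.09, camera adjusted p = 7.96e-09 and 0.292 with an estimated correlation, fry 0.0242). That median was 0.049 after quantile normalisation and 0.037 after cyclic loess. The list members Gpnmb, a lysosomal stress glycoprotein, Ctsl and the folliculin partner Fnip1 lay at 1.27 (adjusted p = 0.0776), 0.30 (adjusted p = 0.169) and 0.30 (adjusted p = 0.164). Chromaffin genes lay lower in 24 of 31 cases, with 0 passing and 12 lower over the list alone (median -0.20, camera adjusted p = 2.91e-10 and 0.292 with an estimated correlation). The nicotinic subunit Chrnb4 lay at -0.57 (adjusted p = 0.167), Dbh at -0.72 (adjusted p = 0.262) and the granin Chgb at -0.29 (adjusted p = 0.197). Fatty acid synthesis genes lay higher in 12 of 15 cases (median 0.19, camera adjusted p = 0.00028 and 0.292 with an estimated correlation), among them the carboxylase Acaca at 0.19, the ligase Acsl3 at 0.24 and the desaturase Fads1 at 0.41, with 0 passing and 1 over the list alone.

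Further lists passed camera for compound 3 with small medians and 0 members past the threshold over all features. Over each list alone 3 epithelial genes, 2 cAMP and CREB targets and 1 each of the neuronal, fibroblast and immediate-early lists were lower, 1 of the metal list was higher, and 0 passed in the others. Lower were neuronal differentiation (median -0.06, camera adjusted p = 0.000428 and 0.292 with an estimated correlation), with Dpysl3 at -0.38 and the intermediate filament Prph at -0.24, and epithelial markers (median -0.06, camera adjusted p = 0.0009 and 0.292 with an estimated correlation), with the keratins Krt8 and Krt18 at -0.42 and -0.41. Histones (median -0.10, camera adjusted p = 0.00173 and 0.572 with an estimated correlation), cAMP and CREB targets (median -0.09, camera adjusted p = 0.00173 and 0.572 with an estimated correlation) and G2/M genes (median -0.05, camera adjusted p = 0.0024 and 0.717 with an estimated correlation) lay lower too, among them Vgf at -0.51, the granin Chga at -0.37 and the mitotic gene Cdca3 at -0.18. The same held for fibroblast markers (median -0.06, camera adjusted p = 0.0108 and 0.572 with an estimated correlation), with the surface glycoprotein Thy1 at -0.47, for DNA replication (median -0.045, camera adjusted p = 0.0289 and 0.717 with an estimated correlation) and for immediate-early genes (median -0.05, camera adjusted p = 0.0458 and 0.572 with an estimated correlation). Higher were the mitochondrial ribosome (median 0.04, camera adjusted p = 0.0111 and 0.572 with an estimated correlation) and the metal list (median 0.09, camera adjusted p = 0.0424 and 0.393 with an estimated correlation), with Tfrc at 0.24. Several of these calls are fragile. In exact permutation tests of list means per array p was 0.5 for G2/M genes and 0.4 each for DNA replication and histones. It was 0.2 for the cAMP and CREB, fibroblast, immediate-early and mitochondrial ribosome lists, and 0.1 for the neuronal, epithelial and metal lists. Of 21 alternatives 9 each lost the immediate-early and metal lists, 7 DNA replication, 5 each the G2/M, histone and mitochondrial ribosome lists and 4 the cAMP and CREB list, and of the lists with larger medians 3 lost fatty acid synthesis and 2 the chromaffin genes. The fibroblast list was lost in 6 of 20 and its median ran from -0.085 to 0.002, and the G2/M median ran from -0.082 to -0.009. The histone median ran from -0.14 to -0.019 and that of cAMP and CREB targets from -0.283 to -0.043. Among single genes that did not pass, Txndc16, a secretory thioredoxin-domain protein, lay at 0.30 (adjusted p = 0.0998), the ribosomal gene Rps16 at 0.60 (adjusted p = 0.0998) and the potassium channel Kcnk3 at -0.34 (adjusted p = 0.0694). Ppp1r15a, Ddit3 and Htt lay at 0.01 (adjusted p = 0.95), 0.12 (adjusted p = 0.83) and 0.10 (adjusted p = 0.845). Ppp1r15b, Atf4 and Hspa5 lay at 0.00, 0.01 and 0.01, and their signs flipped between scalings. Over the 35 lists 14 passed camera, 5 higher and 9 lower, 0 with an estimated correlation and 2 in fry. Without induced DMSO 1 the number was 8.

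**Figure D3:**
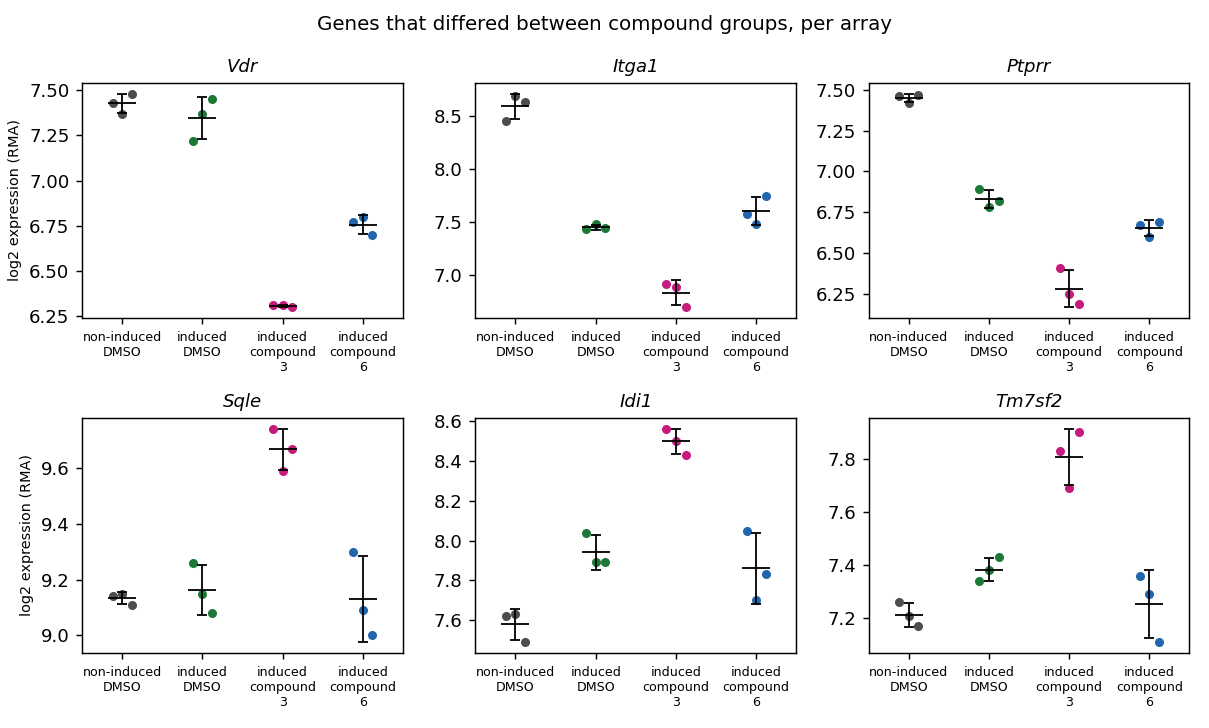
Log2 expression (RMA) of 6 genes on each array in non-induced DMSO, induced DMSO, induced compound 3 and induced compound 6 cells, with points for arrays and bars for the mean ± SD of 3 arrays. Vdr lies at a mean of 7.35 with DMSO, 6.31 with compound 3 and 6.76 with compound 6 in induced cells, and Sqle, Idi1 and Tm7sf2 lie highest with compound 3.

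Compound 6 against vehicle asks the same for the other analogue, and it too lowered the vitamin D receptor. Vdr fell by 0.59 ± 0.06 (95% interval -0.72 to -0.46, adjusted p = 0.0234) and was the single feature that passed, against 1949 at an unadjusted p under 0.05. Arrays did not overlap in 8.04% of features, where chance gives 10%. The call was lost in 14 of the 22 alternatives, 11 of them leaving out 1 array, where induced DMSO 1 was the exception, and its highest adjusted p was 0.893. Below the threshold lay Pdcl2, a phosducin-like protein (0.38, adjusted p = 0.565), Lzts1, a leucine zipper protein (0.20, adjusted p = 0.629), the ring-finger gene Lonrf3 (0.17, adjusted p = 0.721), the corepressor subunit Tbl1xr1 (0.21, adjusted p = 0.796) and Etaa1l1 (0.31, adjusted p = 0.821). On the other side lay Syt5, a synaptotagmin (-0.31, adjusted p = 0.565), the nucleolar gene Ccdc86 (-0.24, adjusted p = 0.629), the Nodal co-receptor Cfc1 (-0.27, adjusted p = 0.629) and Igfbp6, a growth factor binding protein (-0.29, adjusted p = 0.629). Proteasome genes lay lower in 31 of 33 cases with 0 passing, also over the list alone (median -0.08, camera adjusted p = 4.9e-09 and 0.968 with an estimated correlation), such as Psmd8 at -0.22, Psmb5 at -0.18 and Psmb4 at -0.16. Targets of the integrated stress response factor ATF4 lay lower in 41 of 47 cases, again with 0 passing in either count (median -0.08, camera adjusted p = 2.8e-08 and 0.968 with an estimated correlation), such as the serine synthesis genes Phgdh at -0.17 and Psph at -0.19 and the folate enzyme Aldh1l2 at -0.16. DNA replication genes lay higher in 27 of 34 cases with 0 passing in either count (median 0.05, camera adjusted p = 0.00138 and 0.968 with an estimated correlation), with the polymerase subunit Pola1 at 0.18, Chaf1b at 0.13 and Rfc4 at 0.12. These were the 3 lists that passed camera, and fry passed 0. Of the 10 splits of these 6 arrays 8 called at least as many lists, with up to 18 in another split. Exact permutation tests of list means per array gave p = 0.2 for the proteasome, 0.1 for ATF4 targets and 0.4 for DNA replication. Of 21 alternatives 3 lost the proteasome list, 3 the ATF4 targets and 5 DNA replication, whose median ran from 0.012 to 0.076. Without induced DMSO 1, induced DMSO 3 or compound 6 array 2 the number of lists passing camera was 5, 7 and 8. Ppp1r15a lay at -0.11 (95% interval -0.21 to -0.01, adjusted p = 0.876), Ppp1r15b at -0.06 (adjusted p = 0.922) and Ddit3 at 0.03. Hspa5 lay at -0.03, and Atf4 at -0.02 and Htt at -0.02 flipped sign between scalings.

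The direct comparison of compound 6 with compound 3, at the same 10 µM and 48 h, tests whether the analogues differ. They differed in sterol genes. Idi1 was lower with compound 6 by a difference of -0.64 (95% interval -0.82 to -0.45, adjusted p = 0.0426), Tm7sf2 by -0.55 (95% interval -0.71 to -0.40, adjusted p = 0.0426) and Sqle by -0.54 (95% interval -0.70 to -0.37, adjusted p just under 0.05). Higher with compound 6 were Itga1 at 0.76 (95% interval 0.58 to 0.94, adjusted p = 0.023) and Vdr at 0.45 (95% interval 0.32 to 0.58, adjusted p = 0.0426), the latter being the gene that both compounds lowered. The corepressor Tle3 was higher by 0.42 (adjusted p = 0.0426). Just short of the threshold were Rps16 at -0.64 (adjusted p = 0.0596) and the sterol demethylase Cyp51 at -0.60 (adjusted p = 0.0597). In all 15 features passed, 8 higher and 7 lower with compound 6, against 2802 at an unadjusted p under 0.05, and 7 of the 15 carry no gene name. Of these, TC0200002940.rn.1 and TC0200002941.rn.1 have identifiers next to that of the Itga1 feature, TC0200002942.rn.1, and need not be separate genes. Arrays of the 2 groups did not overlap in 14.0% of features, where chance gives 10%. Each of the 8 features with a gene name was lost in some of the 22 alternatives, in 7 for Itga1 and in up to 16 for the others. Leaving out 1 array gave 1 without induced DMSO 2, compound 3 array 1, 2 or 3, or compound 6 array 3. It gave 2 without non-induced 1 or 2 or compound 6 array 2, 3 without compound 6 array 1, 4 without non-induced 3 or induced DMSO 3, and 9 without induced DMSO 1.

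All 21 cholesterol genes lay lower with compound 6 than with compound 3, 3 of them passing and 20 over the list alone (median -0.36, camera adjusted p = 4.42e-25 and 0.217 with an estimated correlation, fry 0.0121). Chromaffin genes lay higher in 27 of 31 cases, 0 passing and 16 over the list alone (median 0.29, camera adjusted p = 2.79e-13 and 0.217 with an estimated correlation, fry 0.0331). Over 21 alternatives that median ran from 0.123 to 0.373. The neurotrophin receptor Ngfr lay at 0.69 (adjusted p = 0.123), Chrnb4 at 0.68 (adjusted p = 0.0895) and Hand2 at 0.55 (adjusted p = 0.127). All 33 proteasome genes lay lower with 0 passing in either count (median -0.11, camera adjusted p = 1.75e-12 and 0.243 with an estimated correlation, fry 0.0395), such as Psmd11 at -0.18 and Psmd6 at -0.15. Lysosome and autophagy genes lay lower in 34 of 39 cases, 15 of them over the list alone against 1 higher (median -0.12, camera adjusted p = 1.92e-09 and 0.217 with an estimated correlation). Gpnmb and the lysosomal genes Ctsd and Ctsa lay at -1.03 (adjusted p = 0.123), -0.31 (adjusted p = 0.147) and -0.28 (adjusted p = 0.127). Fatty acid synthesis (median -0.17, camera adjusted p = 3.31e-06 and 0.217 with an estimated correlation) and ATF4 targets (median -0.08, camera adjusted p = 3.5e-05 and 0.252 with an estimated correlation) lay lower, the latter with the amino acid transporter chain Slc3a2 at -0.26 (adjusted p = 0.124). DNA replication (median 0.07, camera adjusted p = 1.46e-07 and 0.359 with an estimated correlation), with Pold1 at 0.27, and G2/M genes (median 0.09, camera adjusted p = 1.52e-06 and 0.442 with an estimated correlation), with Cdk1 at 0.14, lay higher. Of these 4 lists 0 members passed over all features, and over the list alone 1 ATF4 target was lower. Exact permutation tests of their list means per array gave p = 0.3 for G2/M genes and 0.1 for the other 3.

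The smaller list differences between the analogues had medians of at most 0.10 in size and 0 members past the threshold over all features. Over each list alone 6 cAMP and CREB targets, 4 genes of the REST target list, 3 epithelial genes and 1 neuronal gene were higher, and 0 passed in the others. Higher with compound 6 were cAMP and CREB targets (median 0.08, camera adjusted p = 6.54e-05 and 0.243 with an estimated correlation), neuronal differentiation (median 0.05, camera adjusted p = 6.63e-05 and 0.243 with an estimated correlation), epithelial markers (median 0.05, camera adjusted p = 0.00195 and 0.243 with an estimated correlation), REST targets (median 0.10, camera adjusted p = 0.00329 and 0.243 with an estimated correlation) and histones (median 0.09, camera adjusted p = 0.00343 and 0.442 with an estimated correlation). Their members included Vgf at 0.55, Scn3b at 0.39, Scg2 at 0.42, Dpysl3 at 0.33 and the keratin Krt7 at 0.35, none of which passed. Over 21 alternatives the REST median ran from 0.048 to 0.125, that of histones from 0.01 to 0.132 and that of cAMP and CREB targets from 0.033 to 0.353. Exact permutation tests of list means per array gave p = 0.4 for histones and 0.1 for the other lists that were higher here. Lower were NRF2 targets (median -0.06, camera adjusted p = 0.00273 and 0.387 with an estimated correlation), the mitochondrial ribosome (median -0.05, camera adjusted p = 0.00295 and 0.359 with an estimated correlation), the kinases and phosphatases of eIF2α (median -0.045, camera adjusted p = 0.00343 and 0.243 with an estimated correlation) and ubiquitin and ER-associated degradation (median -0.07, camera adjusted p = 0.00343 and 0.243 with an estimated correlation). The selective autophagy receptor Sqstm1 lay at -0.18, the segregase Vcp at -0.16 and the initiation factor subunit Eif2b1 at -0.14. Oxidative phosphorylation (median -0.03, camera adjusted p = 0.00923 and 0.387 with an estimated correlation) and the unfolded protein response (median -0.03, camera adjusted p = 0.0493 and 0.382 with an estimated correlation) also passed as lower, but the median of the former was higher after cyclic loess and that of the latter after quantile normalisation or cyclic loess. Their calls were lost in 5 and 13 of 21 alternatives, that of histones in 4 and those of DNA replication and G2/M genes in 3 each. Their members included the ER membrane gene Selenos at -0.17 and Ndufb8 at -0.13. Ppp1r15a lay at -0.12 (95% interval -0.22 to -0.02, adjusted p = 0.47) and Ppp1r15b at -0.06 (95% interval -0.15 to 0.03, adjusted p = 0.814). Atf4, Ddit3 and Htt lay at -0.03, -0.09 and -0.12, and Hspa5 at -0.04 flipped sign between scalings. In all 19 lists passed camera, 8 higher and 11 lower with compound 6, 0 with an estimated correlation and 10 in fry.

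The last comparisons ask whether the compounds bring the induced cells back towards the non-induced state. Against non-induced cells Sparc and P2ry12, the induction genes with the largest changes, differed under both compounds. Sparc lay higher by 1.82 (adjusted p = 1e-05) with compound 3 and 1.38 (adjusted p = 0.000227) with compound 6, and P2ry12 lower by a difference of -2.72 (adjusted p = 5.79e-06) and -2.01 (adjusted p = 0.000119). Dbh lay at -1.94 (adjusted p = 3.49e-05) and -1.41 (adjusted p = 0.000872), and Itga1 at -1.75 (adjusted p = 2.27e-06) and -0.99 (adjusted p = 0.000174). Vdr, which induction with vehicle left at -0.08 (adjusted p = 0.496), lay at -1.12 (adjusted p = 5.13e-06) and -0.67 (adjusted p = 0.000227). Idi1 was higher by 0.92 (adjusted p = 5.37e-05) with compound 3, and lay at 0.28 (adjusted p = 0.071) with compound 6. Compound 3 cells differed from non-induced cells in 5216 features, 2870 higher and 2346 lower, a split of 2076 and 2424 after median scaling, and compound 6 cells in 2644, 1231 higher and 1413 lower. For compound 6 the split was 842 and 1354 after median scaling, 2256 and 2018 with array weights, and 1302 and 1151 without non-induced 1. The count for compound 3 was 3465 without non-induced 3. For compound 6 it was 1506 without non-induced 2, 1210 without non-induced 3, 1294 without compound 6 array 2 and 1742 without array 3. Both comparisons called 1109 features higher and 1317 lower together and 0 in opposite directions. The shared non-induced arrays and the induction itself give these comparisons calls in common.

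Against vehicle 8 features were called for compound 3 and 1 for compound 6. No more than these of the 3120 induction features could be called again, so the counts moved back or further say little about reversal. Compound 3 moved 1 of the 3120 back and 4 further, and compound 6 moved 0 either way (limma, 1949 features at an unadjusted p under 0.05). The 1 moved back is an unnamed feature, TC1100000885.rn.1, which fell with induction and rose by 0.52 with compound 3, and the 4 moved further are Itga1, Ptprr, Kcnh3 and the unnamed TC1500001407.rn.1, all singled out after their values were seen. Leaving out any array other than induced DMSO 1 brought the count of features moved back by compound 3 to 0. By sign alone, 33.1% of the induction features lay opposite to induction with compound 3 and 78.6% with compound 6, and 2826 and 2026 of them still differed from non-induced cells. The shared vehicle arrays by themselves push the compound effects against the induction effect, to a simulated covariance of -0.00396, or -0.00777 with the vehicle arrays' own spread. The observed covariance over all features was 0.000901 for compound 3 and -0.00676 for compound 6. Estimated from separate vehicle arrays it was 0.00846 and 0.000802, where a positive value runs in the direction of induction, but the latter was -0.00106 with a stricter filter and -0.00212 without compound 6 array 2. Both compounds shared 1 called feature, Vdr, lower with each, against 0.000174 expected for independent lists, a reference that ignores the shared vehicle arrays. Leaving out any array other than induced DMSO 1 brought that overlap to 0. The covariance of the compound effects was 0.00393, where shared vehicle arrays alone give 0.00396 in simulation and 0.00777 with their own spread, and it was -0.00363 from separate vehicle arrays.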

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

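Of the tests in this part, the correlation with GC-rich background and the fit with that background as a covariate were chosen after seeing the data. The 2 compounds' effects differed in a direct test. Compound 6 minus compound 3 called 15 features, and 10 lists passed both camera and fry: cholesterol biosynthesis (median -0.36), chromaffin and catecholamine genes (0.29), proteasome (-0.11), lysosome and autophagy (-0.12), fatty acid synthesis (-0.17), ATF4 targets (-0.083), neuronal differentiation (0.05), ubiquitin and ER-associated degradation (-0.068), the kinases and phosphatases of eIF2α (-0.045) and the unfolded protein response (-0.033), the last lost in 13 of 21 alternatives. No list passed camera with an estimated correlation, where the lowest adjusted p was 0.217. Outside the main measurement, the GC-rich background probes of induced DMSO 3 read 6.86, which is 0.31 above the highest non-induced array, against 6.46 for induced DMSO 1.

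Cholesterol synthesis had the smallest camera p of the lists that differed between the analogues. A single array does not decide it: over the fits that leave out an array, the list median of compound 3 minus vehicle was at least 0.302, against 0.35 with all arrays. With GC-rich background as a covariate the median was 0.293, so background, as far as this linear covariate measures it, is not its whole cause either. The 3 highest list means of the 9 induced arrays were the 3 compound 3 arrays (lowest 8.78, highest other 8.62). The list was picked for this pattern on the same arrays, so the ranking restates it and decides nothing. An effect of compound 3 on sterol synthesis that compound 6 lacks stays open.

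Induced DMSO had the largest within-group SD, 0.153 against 0.0949 to 0.113. Its arrays 1 and 3 lay on opposite sides of their group mean, but deviations of 3 arrays from their own mean run against each other by construction, so that alone shows no structure. The leading component of the within-group deviations, 39.8% of the variance, followed GC-rich background over 12 arrays (Pearson r 0.935, exact permutation p = 0.0054, Spearman rho 0.902, p = 0.00694, and r 0.792 without the 2 farthest arrays). Array background tied to probe GC is thus a candidate source of that component. For growth state, measured by the G2/M mean, Pearson r was -0.476 (exact permutation p = 0.157) and Spearman rho -0.573 (p = 0.115), which leaves it open.

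Other splits of the arrays were counted for each comparison. The 10 splits of 6 arrays are too few for a share under 0.05. As many features as the real split came from 1 split, the real one, for induction (3120, highest other 0), compound 3 (8, highest other 0), compound 6 against 3 (15, highest other 0) and each compound against non-induced cells (5216 and 2644, highest other 0 for both). For compound 6 against vehicle 2 splits gave as many, with 1 feature in the real split and 124 in the other. That split set induced DMSO 1 and compound 6 arrays 1 and 3, against the remaining arrays, and calling several times the real count points to a structure of the samples. Its sides were the 3 arrays with the lowest GC-rich background (6.46, 6.51 and 6.48) and the 3 with the highest (6.61, 6.86 and 6.58). Background is thus a candidate source. A split of the compound 3 and vehicle arrays with mean backgrounds of 6.49 and 6.68 called 0 features. That split holds other arrays, and any compound 3 effect widens the spread within its sides, so it does not exclude background. For lists, 3 splits gave as many as the real 17 of induction (highest other 20), 2 as many as the 14 of compound 3 (18), 8 as many as the 3 of compound 6 (18) and 1 as many as the 19 of compound 6 against 3 (16). For the F-test 1 of 100 drawn splits, the real one, called 3540 features and the highest other 1788, so a random arrangement of the arrays rarely gives as many. If the replicates of a group are repeats of 1 culture, this test cannot tell a treatment effect from a difference between cultures.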

How the results depend on the processing

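The fits with GC-rich background as a covariate and with 1-symbol features alone were chosen after seeing the data. Vdr with compound 3 passed in all 22 alternatives. The 3120 induction features became 5515 with array weights, 570 with at least 1.5-fold, 2072 with no filter and 1573 with only the 2 groups, and leaving out an array gave 1815 to 5165. The 8 of compound 3 became 4 with the background covariate, 13 with array weights, 5 with at least 1.5-fold, 4 with median scaling, 3 with no filter, 48 with 1-symbol features, 2 with only the 2 groups, 22 with the stricter filter, 18 with trend and robust prior, and 2 to 6 without an array. Against 2 higher and 6 lower, the split was 5 and 7 with quantile normalisation, 9 and 13 with the stricter filter and 8 and 10 with trend and robust prior. The 1 of compound 6 became 3 with array weights, 0 with no filter and with only the 2 groups, and 0 to 1 without an array. The 15 of compound 6 against 3 became 133 with array weights, 8 with at least 1.5-fold, 6 with median scaling, 2 with no filter, 135 with 1-symbol features, 1 with only the 2 groups, and 1 to 9 without an array. Against non-induced cells the 5216 of compound 3 became 885 with at least 1.5-fold and 3465 to 5477 without an array, and the 2644 of compound 6 became 4274 with array weights, 307 with at least 1.5-fold, 1623 with no filter and 1210 to 2938 without an array. The F-test's 3540 became 5761 with array weights, 580 with at least 1.5-fold, 2356 with no filter and 1874 to 4322 without an array. The 1 overlap of the compounds became 0 with no filter and 0 to 1 without an array. The 1 feature that compound 3 moved back became 0 with the covariate, with at least 1.5-fold and with no filter, and 0 to 1 without an array. The number moved back by compound 6 was 0 throughout (limma, 1949 features at an unadjusted p under 0.05). Lists called became 0 in each of the first 4 comparisons with an estimated correlation. With fry 17, 14, 3 and 19 became 20, 2, 0 and 10, and with fry's mixed test 31, 8, 0 and 19. The 3 of compound 6 became 6 with the covariate, 6 with cyclic loess, 5 with the stricter filter and 3 to 8 without an array, and the 14 of compound 3 became 8 to 20 without an array. Counts not given for an alternative stayed within 1.5 times the reported one. When single arrays were left out, 2379 of the named genes' values stayed on their side of the threshold, 208 lost a call and 5 gained one, and for list medians 706, 40 and 10. These tallies include genes and lists that were not called, which cannot lose a call, so they overstate how well the calls held. Signs of the oxidative phosphorylation and unfolded protein response medians between the compounds flipped under cyclic loess, where they were not called. A reversal appeared in the covariance of induction and compound 6 from separate vehicle arrays, -0.00106 with the stricter filter and -0.00212 to 0.00239 without an array (the former without compound 6 array 2), against 0.000802. From separate vehicle arrays the 0.00846 of induction and compound 3 ran from 0.00516 (no filter) to 0.0116 (stricter filter), and the -0.00363 between the compounds from -0.00483 (stricter filter) to -0.00256 (no filter). For the replicate block, the 18 pairs of arrays with the same number had a mean correlation of deviations of 0.147 (-0.169 to 0.452) against -0.0738 for other pairs. Of these 18, 10 were over 0.1, among them all 3 pairs of non-induced and compound 3 arrays and all 6 pairs numbered 1, and 6 of 12 arrays matched their own number best. The numbers are thus not shown to pair all the arrays, and a shared source by number stays open. The replicate block gave 3342 induction features, 2896 of them shared with the 3120, 26 for compound 3 (17 higher and 9 lower), 0 for compound 6, 45 for compound 6 against 3 and an overlap of 0. A fold minimum lowers a count by construction, and testing only the 2 groups leaves fewer arrays for the spread. For the other shifts the cause was not tested. Signal over background limits what is seen: 96 induction features under the filter were called when all features were tested.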

Other observations

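No test in this part was chosen after its result was seen except the fit with GC-rich background as a covariate. Lists that did not pass camera for induction still held genes that changed. Among p53 targets Gadd45a, a DNA damage stress gene, and the death receptor Eda2r rose by 0.69 (adjusted p = 0.00136) and 0.60 (adjusted p = 0.0146), while the polo-like kinases Plk2 and Plk3 fell by 0.70 (adjusted p = 0.0381) and 0.59 (adjusted p = 0.000277). The list split 6 up and 3 down. Interferon-response genes Mx2, an antiviral GTPase, and Tap1, a peptide transporter, rose by 0.47 (adjusted p = 0.000494) and 0.43 (adjusted p = 0.000953), and 4 of 20 rose in all. Of 24 apoptosis genes 4 rose and 2 fell, with a median of 0.037 (camera adjusted p = 0.882). The executioner protease Casp6 and the pore former Bax rose by 0.40 (adjusted p = 0.00115) and 0.26 (adjusted p = 0.0345), and the survival gene Bcl2l1 fell by 0.33 (adjusted p = 0.00176). Of 14 epithelial markers 2 rose and 3 fell, with a median of 0.025 that turned to -0.0083 after median scaling and -0.0028 after cyclic loess (camera adjusted p = 0.455). Among the 3 that fell were the keratins Krt8 and Krt18, by 0.61 (adjusted p = 0.00147) and 0.67 (adjusted p = 0.00694). The chemokine Ccl2, which is not an epithelial marker, fell by 0.66 (adjusted p = 0.00171).

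Stress-response lists did not pass camera after induction, and their medians changed sign with the scaling of the arrays. They lay at 0.003 for ATF4 targets, 0.017 for the unfolded protein response and -0.003 for heat shock genes, at -0.030, -0.017 and -0.037 after median scaling, and at 0.124, 0.096 and 0.089 after quantile normalisation. Among 47 ATF4 targets 4 rose and 3 fell, with the cysteine synthesis gene Cth at 0.65 (adjusted p = 0.000587), the secreted glycoprotein Stc2 at -0.63 (adjusted p = 0.000681) and the mTOR inhibitor Ddit4 at -0.61 (adjusted p = 0.00075), and camera gave an adjusted p of 0.634. Of 36 unfolded protein response genes 4 rose, among them Selenos by 0.30 (adjusted p = 0.00187), the sensor kinase Ern1 by 0.24 (adjusted p = 0.0238) and its target Xbp1 by 0.17 (adjusted p = 0.0322) (camera adjusted p = 0.882). Of 33 heat shock genes 4 rose, among them the co-chaperone Dnajb4 by 0.44 (adjusted p = 0.00188) and the inducible chaperone Hspa1a by 0.30 (adjusted p = 0.0178) (camera adjusted p = 0.882). The polyamine regulator Azin1 fell by 0.40 (adjusted p = 0.000686), the lipid enzyme Acly by 0.25 (adjusted p = 0.0115), and the initiation factor subunit Eif2b1 rose by 0.20 (adjusted p = 0.0308). In the immune and Schwann cell lists 0 genes passed in limma's induction comparison, which called 7245 features at an unadjusted p under 0.05. The genes of this paragraph and the one before were named after their values were seen, except those of the report.

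Compound 3 cells may lie further along the induction change than vehicle cells. To keep the vehicle arrays of both sides apart, features and directions came from compound 6 against non-induced cells (2644), which share no array with compound 3 against vehicle. Compound 3 moved these features by a signed mean of 0.0916 in the direction of induction, 79.2% with that sign (fry p = 0.0122, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The mean was above 0 with separate arrays, but this decides nothing about shared arrays. Sharing pushes a compound effect against induction, so it could not give a shift in this direction. Leaving out an array gave a signed mean of 0.0704 to 0.112, so no single array accounts for the shift. With GC-rich background as a covariate the value was 0.101, so background does not account for it as far as this linear covariate measures it. For compound 6, with the 5216 features of compound 3 against non-induced cells, the signed mean was -0.0313 (fry p = 0.380, exact permutation p = 0.5), which did not pass. A higher level of the fragment under compound 3 is open and not tested.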
